A study of Mus musculus with 6 samples.

How the data were processed

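The intensity values came from 1 scan per array in a single colour, made per the file headers with Agilent Feature Extraction 10.7.3.1 on array design 026655. Per the file headers, the software subtracted background with spatial detrending and gave spots not above background a small positive surrogate, with no scaling between arrays. The deposited log2 values of the authors' table covered 24158 non-control probes. How they were made is not stated. Set against the scanner signal they correlated above 0.999 on each array (Pearson's r, across probes, which are not independent replicates) and had nearly equal distributions between arrays, as quantile normalization gives. The other deposited columns used were flags for spots well above background, saturated or outlying, made by the scanner software per the file headers.

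The processed signal was put on the log2 scale and each array's 75th percentile over non-control spots was subtracted. Spots flagged as outliers were left out, and the spots of a probe were averaged. Probes were kept if well above background on at least 3 of the 6 arrays, which left 26848 of 39429. Symbols were assigned through the RefSeq accession given for each probe, with versions removed, in a gene table of assembly GRCm38.p6, while the file headers name mm9, so no positions are printed. Of the probes, 26424 had a symbol and 13005 did not. Those of the latter that were kept were tested under the accession or other target name given for them, which made 6567 entries. The brightest kept probe stood for each gene, giving 21800 genes tested, 15233 of them with a symbol.

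Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and data held with data.table version 1.17.8. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, two-sided. All adjusted p values for genes in the text are from limma. Log2 changes are null minus wild type, and SE is the moderated standard error. For a gene not well above background on any array of a group, the change is given as a bound against the lowest signal called well above background. Such a bound depends on the background correction and is no lower limit under another one. An exact permutation test of 3 against 3 pools cannot go below 0.1 and was not used for single genes.

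There were 36 gene lists, of which 34 had at least 5 measured members and were tested with camera at a preset correlation of 0.01, adjusted over the 34. Camera with an estimated correlation and fry were run beside it. With camera at the preset correlation 11 lists passed, 8 up and 3 down. With an estimated correlation 0 passed (6 had an unadjusted p under 0.05, the smallest being 0.00706), and with fry 13 passed. The correlation was estimated from only 6 arrays, which leaves that version little power. The lists held 694 genes, of which 650 were measured, 109 rose and 30 fell.

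The arrays were named as pools 1 to 3 in each group, and each slide held the wild-type and the null pool of the same number. Whether the numbers pair the samples was checked by the correlation across genes of each array's deviation from its group mean, which was -0.41, -0.09 and -0.41 for the pools of the same number. Pools of the same number thus did not deviate alike, while wild-type pool 3 and null pool 1, on different slides, reached 0.49. With 3 pools per group, this check cannot show that the slides had no effect. The groups were compared without a block, with the slide as a block given as an alternative.

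The genes named were all Arid3b probes, the 15 largest rises and the 15 largest falls among called genes whose groups did not overlap, skipping names that only denote a clone, and up to 4 called members of each list with the smallest p. Where a list had no called member, the 2 with the smallest unadjusted p are given as values. Another 16 genes were named whatever their values: Lims2, Bhlhe40, Isl1, Tbx1, Fgf8, Fgf10, Bmp2, Bmp4, Tbx2, Nppa, Nkx2-5, Hand2, Wnt11, Wnt5a, Snai1 and Twist1. Genes named outside this rule are marked in the text. A few genes that the rule takes are not reported here.

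The alternatives were quantile normalization, scaling to each array's median, normexp background correction with an offset of 50, no filter on dim probes, only probes well above background on all 6 arrays, outlier spots kept, the mean of a gene's probes, a trended and robust prior, array weights, the slide as a block, the authors' value table and leaving out each of the 6 arrays. The comparison, the lists, the rule for named genes and these alternatives were chosen before the data were examined, except that normexp was run on the median spot signal because the files used here held no mean signal. The trophoblast, ATF4 target and endocrine pancreas lists and the neuron and neural progenitor markers were drawn up after the data were seen.

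In 20 runs on simulated data with 21800 genes, the procedure recovered 0.4% of genes shifted by 0.5 log2 units, 26.6% of those shifted by 1, 76.7% by 2 and 92.2% by 3, and 5.5% of its calls were false. A shifted list was called in 100% of runs, with 0.1 unshifted lists called per run. Each simulated gene varied independently of the others. The runs therefore cannot show how often genes or lists are falsely called where genes vary together.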

Results

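Gene expression was measured on 6 Agilent single-colour mouse arrays in hearts taken from embryos at embryonic day 9.5. Each heart included the heart tube and the mesoderm and endoderm of the pharynx under it. Of the 6 samples, 3 came from wild-type embryos and 3 from embryos without a working Arid3b gene, and each sample was a pool of 4 embryos. Arid3b is a DNA-binding protein with an AT-rich interaction domain. Per array, between 27136 (null pool 3) and 31039 (wild-type pool 3) of 43020 non-control spots were well above background, and no spot was saturated. The 75th percentile of log2 signal was 9.5, 9.57 and 10.16 on the wild-type arrays and 9.47, 9.29 and 9.02 on the null arrays. The small number of arrays, 3 per group, limits the precision of every value below. The arrays lay on 3 slides, each holding 1 wild-type and 1 null pool of the same number, and the wild-type array took the same place on every slide. Place on the slide and genotype therefore cannot be told apart.

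Arid3b itself was lower in every null pool than in every wild-type pool. The brightest of its 3 probes read 2.91, 3.4 and 3.69 in wild-type pools 1, 2 and 3, in log2 units relative to the array's 75th percentile, and 1.07, 0.52 and 0.45 in null pools 1, 2 and 3. The group means were 3.33 ± 0.40 and 0.68 ± 0.34 (SD, n = 3 pools each). The log2 change of -2.65 (SE 0.26) is a fall of 6.28-fold with a limma adjusted p = 0.00192, and with the slide as a block adjusted p = 0.00656. Within slides 1, 2 and 3 the null array lay at -1.83, -2.88 and -3.24 against its wild-type neighbour. The other 2 probes changed by -4.02 and -2.58, and each was well above background on 2 of the 3 null arrays. Whether a probe lies inside the deleted part of the gene is not given in the sources used here, so the signal left on the null arrays says nothing about which transcripts remained.

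**Figure D1:**
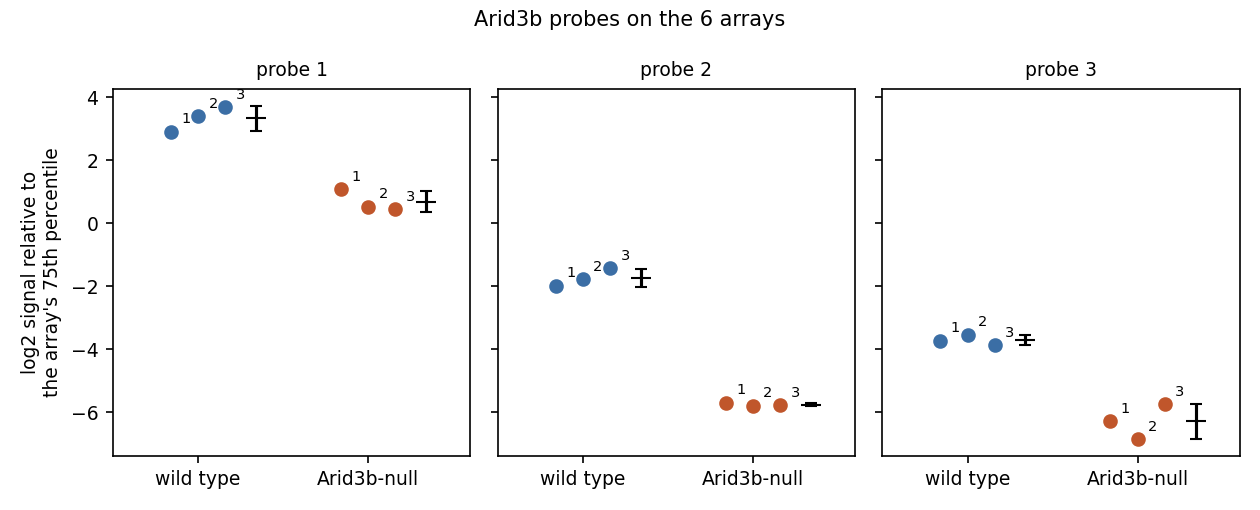
Signal of the 3 Arid3b probes on each array, in log2 units relative to that array's 75th percentile, with wild-type pools in blue and null pools in orange, pool numbers beside the points, and bars for the mean and SD of 3 pools. On each probe the 3 null pools lie below the 3 wild-type pools, and on the brightest probe the means are 3.33 and 0.68.

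The comparison of null with wild-type hearts asks which genes differ in level between hearts with and without Arid3b at this stage. Each pool holds mixed tissue, so a difference can also come from cell makeup or the condition of the embryos. Which changed genes depend on Arid3b within a cell was not tested. In the null hearts, 25 of 30 measured genes of the hypoxia and glycolysis list rose, as did all 14 of the megakaryocyte and platelet list and 12 of 19 immediate early genes. In the cell cycle, cholesterol and neural lists, 5 of 30, 2 of 17 and 3 of 15 genes fell and 0 rose. Without wild-type pool 2, and likewise without null pool 2, the counts were 6 immediate early, 1 cell cycle, 0 cholesterol and 1 neural gene. These 6 lists passed camera with a preset correlation, but none did with an estimated correlation (adjusted p = 0.214, and 0.215 for the neural list). Most genes of the contractile apparatus and of the cardiac transcription factor list did not pass the test. Of 21800 genes tested, 2273 passed an adjusted p under 0.05, of which 1439 were higher and 834 lower in the null pools. Among them, 880 rose and 392 fell by more than 1 log2 unit. The groups did not overlap for 32.9% of the genes tested, where chance gives 10%, and for 2272 of the 2273 changed genes. Where groups do not overlap, the sign within each of the 3 slides is the same by construction. With the slide as a block, 731 genes passed (532 higher and 199 lower), of which 718 were also in the 2273. With each array scaled to its median the split turned to 1093 higher and 1435 lower, and the median change over all genes moved from 0.03 to -0.11, so the number of risen against fallen genes depends on the scaling. The count was 1037 with no filter on dim probes, 4870 with array weights, 836 without wild-type pool 2, 1086 without wild-type pool 3, 901 without null pool 2 and 1105 without null pool 3.

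The hypoxia and glycolysis list rose nearly as a whole. Of its 30 measured members, 25 rose, 0 fell and 5 did not pass, and adjusted over the list alone all 30 rose. Car9, a cell-surface carbonic anhydrase, rose 21.8-fold (log2 4.45, SE 0.18, adjusted p = 0.000158), from -3.61 ± 0.22 to 0.84 ± 0.15 (SD, n = 3). Ndrg1, a stress-responsive gene, rose by 4.38 log2 units (SE 0.20), Egln3, an oxygen-dependent prolyl hydroxylase, by 2.97 (SE 0.17), and Ankrd37 by 2.66 (SE 0.15). The transcription factor Bhlhe40 rose 8.92-fold (log2 3.16, SE 0.23, adjusted p = 0.000715). With the slide as a block 18 of the members passed. The list median was 1.81, and 1.95, 1.58 and 1.75 within slides 1, 2 and 3. The camera test with a preset correlation gave adjusted p = 5.86e-25, and 3.07e-27 with the slide as a block. With an estimated correlation the adjusted p = 0.214, so that call did not hold, and no list passed with an estimated correlation.

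Ndufa4l2, a mitochondrial protein induced by hypoxia, had the largest log2 rise among the named genes, 32.0-fold (log2 5.0, SE 0.17, adjusted p = 0.000141). The 15 largest rises, with Sncb as a bound only, ran from 3.78 to 5.0 log2 units with SEs from 0.17 to 0.49, and the largest adjusted p among them was 0.00324. They included the secreted protein Vgf (4.93), the glutathione-degrading enzyme Chac1 (4.54), the cationic amino acid transporter Slc7a3 (4.43), the peptide hormone Adm2 (4.34), the glycolytic enzyme Eno2 (4.14), the pseudokinase Trib3 (4.0), the lectin Lgals3 (3.82), the secreted glycoprotein Stc2 (3.82) and Nrn1 (3.78). Car9, Ndrg1 and Ppbp also belonged to the 15. Vgf was well above background on 1 wild-type array. Sncb, which encodes a synuclein, was not well above background on any wild-type array and was at least 6.66-fold higher in the null pools (adjusted p = 0.000309). All 15 passed with the slide as a block and with any 1 of the 6 pools left out.

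All 14 members of the megakaryocyte and platelet list rose, with a median of 2.52 and medians of 2.41, 2.67 and 2.22 within slides 1, 2 and 3. Pf4, platelet factor 4, rose 12.6-fold (log2 3.65, SE 0.32, adjusted p = 0.00132), from 1.70 ± 0.57 to 5.35 ± 0.36 (SD, n = 3). Ppbp, a platelet chemokine gene of the same list, rose by 4.28 (SE 0.49), and the platelet receptors Gp6 and Gp1ba by 3.06 (SE 0.23) and 2.65 (SE 0.16). The list passed camera with adjusted p = 1.39e-15, all 14 members passed with the slide as a block, and the adjusted p = 0.214 with an estimated correlation.

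Transcripts of other blood, liver and placental cells differed between pools. Of 26 measured primitive erythroid genes, 4 rose and 0 fell, and 15 rose adjusted over the list alone. Over all genes, 11 rose with normexp, 17 with array weights, 2 with no filter on dim probes and 1 with the slide as a block. The 4 were the transcription factors Gfi1b (1.6, SE 0.26), Gata1 (1.42, SE 0.27) and Nfe2 (1.31, SE 0.27), which megakaryocytes also use, and the heme synthesis enzyme Cpox (1.03, SE 0.17). The list median was 0.96, but 0.40, 1.84 and 0.26 within slides 1, 2 and 3. It passed camera (adjusted p = 1.54e-05) but neither fry (adjusted p = 0.104) nor camera with an estimated correlation (adjusted p = 0.534), and 0 of the members passed without wild-type pool 2, 1 without null pool 2, 3 without wild-type pool 3 and 6 without null pool 3. With the slide as a block, Gfi1b passed and Gata1, Nfe2 and Cpox did not (adjusted p from 0.0651 to 0.0795), and Gata1 and Nfe2 did not pass with no filter on dim probes (0.0527 and 0.0655). Of 17 measured hepatic and visceral endoderm genes, 4 rose and 0 fell: the retinol carrier Rbp4 (2.36, SE 0.19), the transcription factor Hnf4a (2.27, SE 0.24), alpha-fetoprotein Afp (3.56, SE 0.67) and the apolipoprotein Apoe (0.86, SE 0.15). In all, 6 rose adjusted over the list alone. Its median was 0.71, and 0.64, 0.72 and 0.98 within the slides, with camera adjusted p = 0.0120, and adjusted p = 0.347 with an estimated correlation. Without null pool 3 the median was 0.47 and 6 rose. The call of the list was lost with no filter on dim probes (adjusted p = 0.0782), with only probes above background on all 6 arrays (0.0925) and with array weights (0.0575), Afp lost its call without wild-type pool 3 (adjusted p = 0.0634), and Apoe lost its call with the slide as a block (0.11) and without wild-type pool 2, null pool 2 or null pool 3 (up to 0.0661). Of 14 measured macrophage genes, 2 rose and 1 fell: Fcer1g by 1.91 (SE 0.26), Laptm5 by 1.81 (SE 0.35) and the lysozyme Lyz1 by -0.97 (SE 0.20), with 3 and 1 adjusted over the list alone, a median of 0.35 and camera adjusted p = 0.208 (0.0415 with normexp). Laptm5 lost its call without any of the wild-type pools (adjusted p up to 0.0685) and Lyz1 without any of the 6 pools (up to 0.0795). Both lost theirs with no filter on dim probes, and Lyz1 also with normexp (0.0890) and with the slide as a block (0.109). A trophoblast list, drawn up after the data were seen, had 0 of 13 measured members past the threshold, but its mean score relative to wild type was -0.06 in null pool 1, 1.33 in null pool 2 and 4.85 in null pool 3. Prl3d1, a placental lactogen of trophoblast giant cells, read -3.16 ± 0.15 in the wild-type pools (SD, n = 3) and -3.21, -0.97 and 4.78 in null pools 1, 2 and 3.

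**Figure D2:**
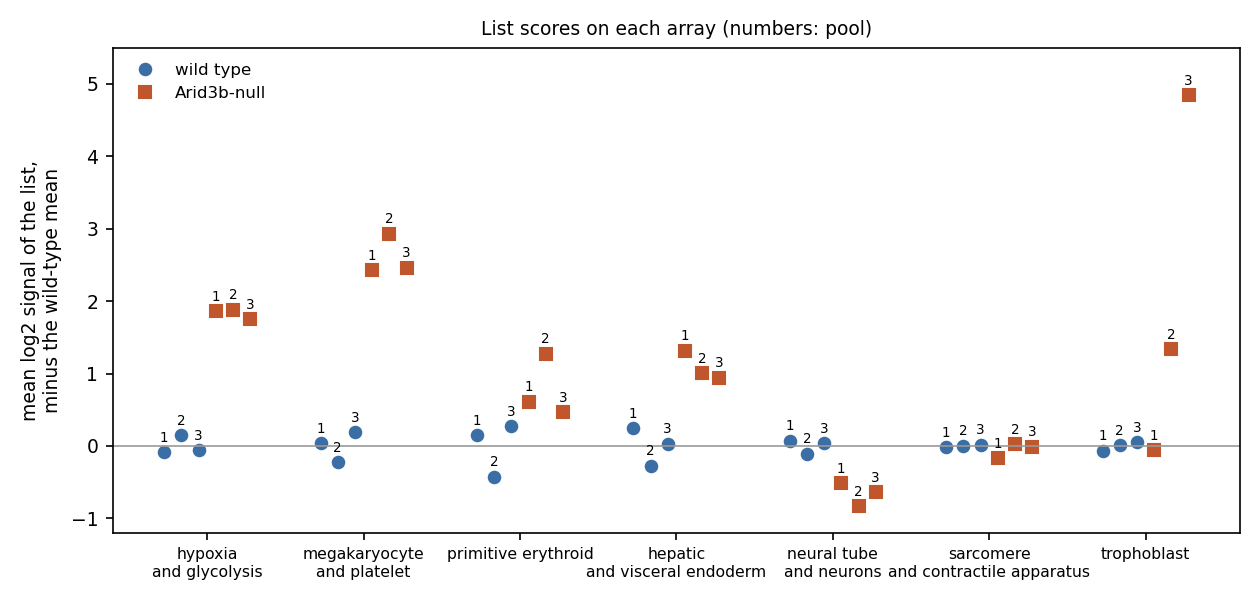
Mean log2 signal of the measured members of 7 lists on each array, minus the mean of the 3 wild-type pools, with circles for wild-type pools, squares for null pools and the pool number above each point. The platelet scores of the null pools are 2.43, 2.93 and 2.46, while the trophoblast scores are -0.06, 1.33 and 4.85.

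The list of immediate early genes passed camera, while the other lists of stress genes did not. Of 19 measured immediate early genes, 12 rose and 0 fell, and 13 rose adjusted over the list alone. The count was 6 without wild-type pool 2 or null pool 2, 7 without wild-type pool 1 or 3 or null pool 1, 9 without null pool 3, 7 with median scaling, 6 with no filter on dim probes and 5 with the slide as a block. Ier3 rose 11-fold (log2 3.46, SE 0.20, adjusted p = 0.000309), the transcription factors Egr2 and Egr1 by 2.73 (SE 0.35) and 1.75 (SE 0.26), and the matrix protein gene Ccn2 by 2.01 (SE 0.24). Their median was 0.99, and 1.22, 1.09 and 0.71 within the slides, with camera adjusted p = 5.24e-08, and adjusted p = 0.214 with an estimated correlation. In the heat shock and unfolded protein response list, 6 of 17 measured members rose and 1 fell, while the list did not pass camera (adjusted p = 0.150, and 0.00965 with fry) and its median of -0.04 and mean of 0.76 differed in sign. The risen members with the smallest p were Chac1, Trib3, Ddit3 (1.96, SE 0.22) and the asparagine synthetase Asns (1.53, SE 0.20), all known targets of the transcription factor ATF4, and the fallen member, named after its value was seen, was the chaperone Hsph1 (-1.17, SE 0.25), whose call ended without any pool but null pool 1, with no filter on dim probes and with the slide as a block. In this list 6 rose and 1 fell adjusted over the list alone. Of 24 measured p53 target and apoptosis genes, 8 rose and 0 fell over all genes tested, and adjusted over the list alone 8 rose and 2 fell. The risen were 3 without wild-type pool 2, without null pool 2 or with the slide as a block, 5 without wild-type pool 3 or null pool 3 and 4 with no filter on dim probes, and with median scaling 6 rose and 2 fell, with normexp 7 and 2. The 8 included the secreted stress factor Gdf15 (2.03, SE 0.23), the BH3-only genes Pmaip1 (1.31, SE 0.18) and Bbc3 (0.93, SE 0.15) and the stress-induced Sesn2 (1.28, SE 0.20). This list's median was 0.09 with camera adjusted p = 0.127, and it passed with quantile normalization (0.0476) and with fry (0.0056). Bbc3 lost its call without wild-type pool 2 or null pool 2 (adjusted p up to 0.0557) and with the slide as a block (0.0900).

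The cell cycle, cholesterol and neural lists passed camera with a preset correlation, with few called members. Of 30 measured cell cycle genes, 5 fell and 0 rose, over all genes and adjusted over the list alone, and 8 fell with array weights and 2 with no filter on dim probes. The 5 included the cyclins Ccnd1 (-0.91, SE 0.15) and Ccne1 (-1.17, SE 0.20) and the nucleotide synthesis enzymes Tyms (-0.89, SE 0.16) and Rrm2 (-1.09, SE 0.22). The other was the cyclin Ccnd2 (-0.62, SE 0.16), named after its value was seen. Its median was -0.32, and -0.41, -0.40 and -0.31 within the slides, with camera adjusted p = 1.54e-05, and adjusted p = 0.214 with an estimated correlation. Of 17 measured cholesterol biosynthesis genes, 2 fell and 0 rose, among them the enzyme Fdps by -0.95 (SE 0.16), and 4 fell adjusted over the list alone. Over all genes, 4 fell with median scaling or a trended prior, 5 with normexp or the mean of probes and 9 with array weights, but 1 with no filter on dim probes or without wild-type pool 3 and 0 without null pool 3. That list's median was -0.58, and -0.51, -0.70 and -0.51 within the slides, with camera adjusted p = 3.85e-05, and adjusted p = 0.214 with an estimated correlation. Of 15 measured neural tube and neuron genes, 3 fell and 0 rose, while 5 fell and 1 rose adjusted over the list alone. Tubb3, a neuronal tubulin, fell by 1.16 log2 units (SE 0.25) and the microtubule protein Dcx by 1.31 (SE 0.26) on its brightest probe, with 0.03 on its other probe. The neural list median was -0.43, and -0.39, -0.27 and -0.32 within the slides. It passed camera (adjusted p = 0.00983) but not with normexp background correction (adjusted p = 0.0874), nor with an estimated correlation, where the adjusted p = 0.215. With the slide as a block no cell cycle or cholesterol gene and 1 neural gene passed, and the named calls of these lists other than that of Neurod1 ended without null pool 2, without wild-type pool 2 or without both in turn (largest adjusted p 0.0974). Dcx and Tyms also lost their calls with normexp (adjusted p = 0.286 and 0.0523), and Dcx, Tubb3, Rrm2 and Tyms with no filter on dim probes (up to 0.0768).

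The largest adjusted p among the 15 largest fitted falls, which include Arid3b, was 0.0193. The neural tube transcription factor Nkx1-2 fell by 3.07 (SE 0.32) on its brightest probe, with -0.50 on its other probe. Nkx6-1, a transcription factor of neural progenitors and pancreatic beta cells, fell by 2.90 (SE 0.26, adjusted p = 0.00141), the sodium channel subunit Scn4b by 2.48 (SE 0.23), the pancreatic lipase-related Pnliprp1 by 2.39 (SE 0.33), the muscle caveolin Cav3 by 2.35 (SE 0.21), the neuronal protein Tagln3 by 2.33 (SE 0.22) and Btbd17 by 2.27 (SE 0.43). Nkx1-2 and Btbd17 were well above background on 1 null array each. Another 7 were not well above background on any null array, so that only bounds can be given. The hemojuvelin gene Hjv was at least 4.04-fold lower in the null pools, Neurod1, a transcription factor of neurons and endocrine cells, at least 3.37-fold, Olig3 at least 2.11-fold, Hs3st2 at least 1.91-fold, Ppcdc at least 1.85-fold, the glucagon gene Gcg at least 1.45-fold and Mat1a at least 1.11-fold. These 7 lost their calls with normexp background correction (adjusted p from 0.224 to 0.982), where Gcg, Ppcdc and Mat1a also turned in sign. Btbd17 lost its call with normexp (adjusted p = 0.127) and without wild-type pool 2, null pool 2 or null pool 3 (adjusted p up to 0.0782). Ppcdc lies near Arid3b on the same chromosome in the GRCm38.p6 gene table.

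No list of heart muscle genes passed camera in the main comparison. Of 29 measured sarcomere genes, 1 rose and 1 fell: Myom2 by 1.59 (SE 0.16) and the myosin chaperone Unc45b by -1.26 (SE 0.16). Its median was -0.08 (camera adjusted p = 0.535, and 0.0439 with normexp). Of 22 cardiac transcription factors, 2 fell and 0 rose, Irx4 by -0.82 (SE 0.16) and Smyd1 by -0.72 (SE 0.15), with a list median of -0.08 (adjusted p = 0.181, but 0.0330 with normexp and 0.0348 with no filter on dim probes). Nkx2-5 had a log2 difference of 0.07 (SE 0.16, adjusted p = 0.827) and Hand2 of -0.52 (SE 0.29, adjusted p = 0.306). In the chamber myocardium list 3 of 19 measured members rose and 1 fell. The natriuretic peptide genes Nppb and Nppa rose by 1.82 (SE 0.22, adjusted p = 0.00431) and 1.27 (SE 0.18, adjusted p = 0.00775), Nppa from 6.51 ± 0.08 to 7.77 ± 0.27 (SD, n = 3), and Bmp10, a growth factor of trabeculae, rose by 0.95 (SE 0.17). The chamber list median was 0.26 (camera adjusted p = 0.150). Of 24 measured calcium handling and ion channel genes, 1 fell and 1 rose, the calcium channel Cacna1d by -1.42 (SE 0.17) and Asph by 0.58 (SE 0.15), with a median of 0.03, a mean of -0.05 and camera adjusted p = 0.736. Cacna1d had an adjusted p = 0.0508 with normexp background correction. Of 14 atrioventricular canal genes, 1 fell and 0 rose, with a median of -0.11 and camera adjusted p = 0.433. That gene, the Wnt agonist Rspo3, fell by 1.49 (SE 0.21, adjusted p = 0.00745), while Bmp2 at -0.04 (SE 0.20), Bmp4 at 0.20 (SE 0.17) and Tbx2 at -0.65 (SE 0.20) did not pass. Tbx2 passed with median scaling (adjusted p = 0.0352) and normexp (0.0354). Adjusted over the list alone, the counts risen and fallen were 1 and 1 for sarcomere genes, 0 and 2 for cardiac transcription factors, 3 and 1 for chamber genes, 1 and 2 for calcium handling genes and 1 and 1 for canal genes. The calls of Irx4, Smyd1, Bmp10 and Asph ended with the slide as a block (adjusted p from 0.0862 to 0.263) and each ended without wild-type pool 2, wild-type pool 3 or null pool 2 (up to 0.16 with any pool left out). Irx4, Smyd1 and Asph also lost theirs with no filter on dim probes (up to 0.127), Smyd1 with the mean of probes (0.0622) and Asph with median scaling (0.0964).

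Of 26 measured genes of the second heart field and pharyngeal mesoderm, the precursors that add muscle to the growing heart tube, 1 fell and 0 rose, over all genes and adjusted over the list alone. Osr1 fell by 0.96 (SE 0.17, adjusted p = 0.0153), with adjusted p = 0.0803 with the slide as a block and up to 0.0696 without wild-type pool 2, wild-type pool 3 or null pool 2. The genes that did not pass included Isl1 at -0.36 (SE 0.22, adjusted p = 0.349), Tbx1 at 0.30 (SE 0.23, 0.446), Fgf8 at 0.90 (SE 0.25, 0.0669), Fgf10 at 0.59 (SE 0.20, 0.109), Wnt11 at -0.70 (SE 0.27, 0.152) and Wnt5a at -0.16 (SE 0.19, 0.639). The list median was 0.14 (camera adjusted p = 0.623). In the neural crest and arch mesenchyme list, 1 of 26 measured members rose and 1 fell, Tfap2a by 0.91 (SE 0.17) and Dlx1 by -1.13 (SE 0.19), with a median of 0.05, a mean of -0.01 and camera adjusted p = 0.827. In the pharyngeal endoderm and epithelium list, 4 of 25 rose and 3 fell, with a median of -0.07, a mean of 0.04 and camera adjusted p = 0.827. Of the fallen, 1 was left without wild-type pool 2 or 3 or null pool 2. The keratin genes Krt19 and Krt18 rose by 3.03 (SE 0.19, adjusted p = 0.000407) and 1.09 (SE 0.16), Sox17 rose by 1.22 (SE 0.16), and the pharyngeal transcription factor Nkx2-6 fell by 1.09 (SE 0.17, adjusted p = 0.0105). The other 3, named after their values were seen, were Pax8 (0.91, SE 0.22), Ripply3 (-1.24, SE 0.27) and Nkx2-1 (-0.79, SE 0.20). None of these 3 passed with the slide as a block. Pax8 also lost its call without wild-type pool 1 or 2 or null pool 2 or 3. The same held with median scaling and with no filter on dim probes. Adjusted over the list alone, 2 neural crest genes rose and 1 fell, and 6 endoderm genes rose and 6 fell. Krt18 and Nkx2-6 did not pass with the slide as a block (adjusted p = 0.0649 and 0.0668), nor did Tfap2a and Dlx1 (0.109 and 0.0649), whose calls also ended without null pool 2 (adjusted p up to 0.0744). Dlx1 lost its call with normexp as well (adjusted p = 0.141) and Tfap2a with no filter on dim probes (0.0608).

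Genes of cell adhesion and of the epicardium passed camera with a preset correlation. Of 30 measured integrin adhesion and cell motility genes, 3 rose and 0 fell, over all genes and adjusted over the list alone. Lims2, an adaptor at integrin adhesions, rose 7.56-fold (log2 2.92, SE 0.23, adjusted p = 0.000978), from -0.98 ± 0.36 to 1.94 ± 0.26 (SD, n = 3). The collagen receptor Itga1 rose by 1.02 (SE 0.16) and Fblim1 by 0.71 (SE 0.17), and these did not pass with the slide as a block (adjusted p = 0.0658 and 0.204) or without null pool 2 (adjusted p up to 0.106). Fblim1 also lost its call with median scaling (0.0913) and no filter on dim probes (0.109), and with array weights 6 of the list rose and 1 fell. The list median was 0.31, and 0.52, 0.23 and 0.12 within the slides, with camera adjusted p = 0.0131, and adjusted p = 0.428 with an estimated correlation. The call also ended without wild-type pool 1 (adjusted p = 0.180), without null pool 1 (0.192), with normexp (0.210), with no filter on dim probes (0.164) and with array weights (0.0921). Of 12 epicardial genes, which mark the outer layer of the heart and its precursor, 3 rose and 0 fell, and 5 rose adjusted over the list alone. They were Krt19, the transcription factor Wt1 (1.42, SE 0.24, adjusted p = 0.0129) and mesothelin, Msln (0.93, SE 0.22). Krt19 is also counted in the pharyngeal endoderm and epithelium list, so its rise cannot be assigned to either tissue. The epicardial median was 0.53, and 0.64, 0.87 and 0.31 within the slides, with camera adjusted p = 0.0216, adjusted p = 0.406 with an estimated correlation and adjusted p = 0.158 without null pool 1, and the call ended with no filter on dim probes (0.113) and with array weights (0.0681). Wt1 lost its call without wild-type pool 2 or 3 (adjusted p up to 0.0578) and Msln with the slide as a block (adjusted p = 0.125), without any pool but wild-type pool 1 (up to 0.120), with no filter on dim probes (0.0951) and with a trended prior (0.0644).

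**Figure D3:**
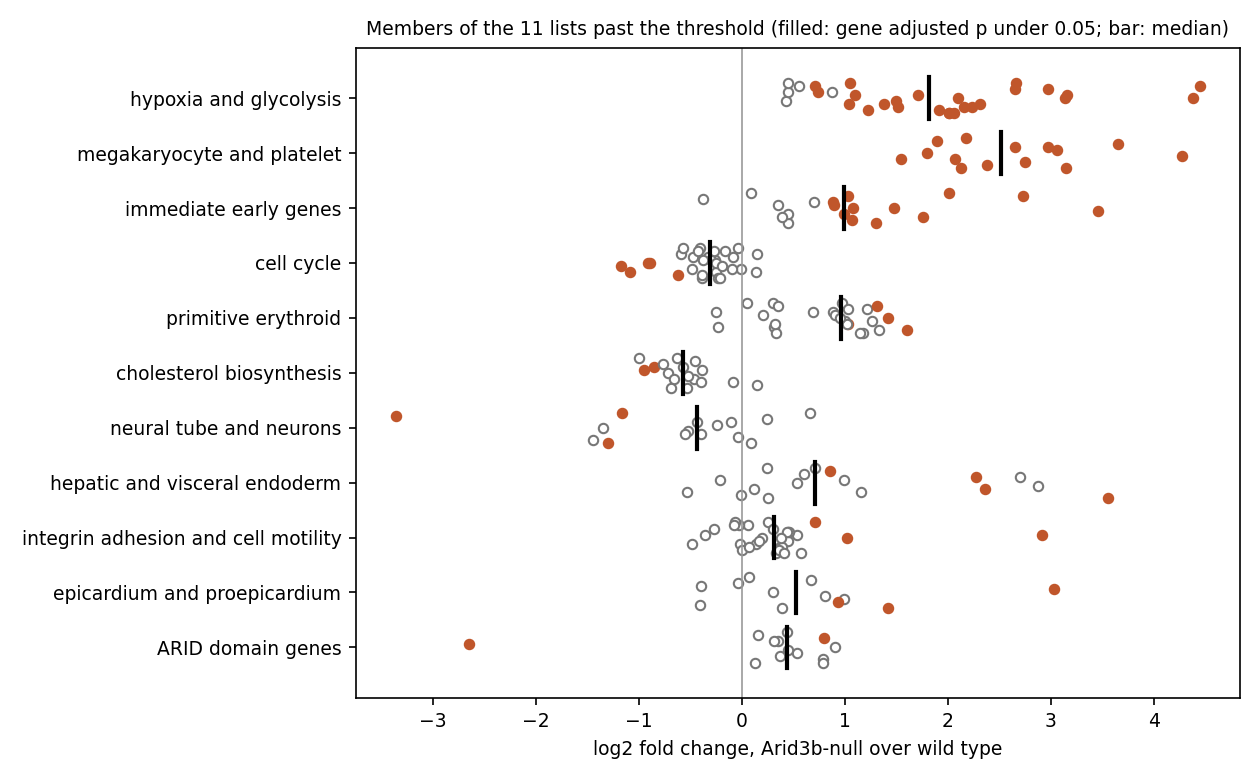
Log2 fold change of null over wild type for each measured member of the 11 lists that passed camera with a preset correlation, with filled points for genes with an adjusted p under 0.05 and a bar at the list median, Neurod1 being drawn at its fitted value although no null array was well above background. The medians are 1.81 for hypoxia and glycolysis, 2.52 for megakaryocyte and platelet, 0.99 for immediate early genes and -0.32 for the cell cycle.

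Endothelial, mesenchymal and muscle lists did not pass camera in the main comparison. Of 30 endocardial and endothelial genes, 3 rose and 1 fell, the transcription factors Sox17, Erg (1.21, SE 0.22) and Sox7 (1.34, SE 0.26) rising and Etv2 falling by 0.93 (SE 0.19), with a median of 0.18 and adjusted p = 0.181 (0.0494 with fry). The risen endothelial genes were 6 without null pool 1, with quantile normalization or with a trended prior, 9 with array weights and 5 with normexp, with only probes above background on all 6 arrays or with the authors' value table, but 1 without wild-type pool 2 or null pool 3. Of 28 cushion mesenchyme and matrix genes, 2 rose and 0 fell, the collagen gene Col6a1 by 1.56 (SE 0.21) and Tgfb1 by 1.09 (SE 0.28), with a median of 0.25 and adjusted p = 0.150 (0.0476 with quantile normalization). Snai1 and Twist1, transcription factors of the change from epithelium to mesenchyme, did not pass, at -0.31 (SE 0.17, adjusted p = 0.292) and 0.55 (SE 0.35, adjusted p = 0.355). Of 12 smooth muscle genes, 2 rose and 1 fell, Tagln by 0.79 (SE 0.15), Tpm2 by 0.82 (SE 0.17) and Lmod1, which was not well above background on any null array, at least 1.62-fold lower, with a median of 0.05 and adjusted p = 0.762. Of 7 measured skeletal myogenic genes, 1 fell, the embryonic myosin Myh3, given without a size because its brightest probe was not well above background on any null array, with a median of -0.14 and adjusted p = 0.535. Adjusted over the list alone, the counts risen and fallen were 6 and 2, 1 and 0, 2 and 1, and 1 and 1 in this order. Of the genes in this paragraph with a call, Sox17 and Col6a1 kept theirs with the slide as a block and with each pool left out, and the others lost theirs with the block (adjusted p from 0.055 to 0.146) and without wild-type pool 2 (up to 0.159 with any pool left out). Lmod1 and Myh3 turned in sign with normexp background correction. With no filter on dim probes Sox7, Etv2, Tgfb1, Tagln, Tpm2, Lmod1 and Myh3 lost their calls (adjusted p up to 0.107), as did Tgfb1 and Tpm2 with median scaling, Lmod1 and Myh3 with a trended prior and Myh3 with the mean of probes (up to 0.272). With array weights 7 cushion genes rose.

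Among signalling pathways no list passed camera, the smallest adjusted p being 0.0667 for the FGF and ERK list, in which 0 of 17 genes passed and Dusp4 and Fgf8 had the smallest p (log2 0.92, SE 0.25, and 0.90, SE 0.25). The FGF list passed with quantile normalization (adjusted p = 0.0232), without wild-type pool 2 (0.0119) and without null pool 2 (0.0265), and Dusp4 and Fgf8 passed with normexp (0.0296 and 0.0387) and a trended prior (0.0359 and 0.0377). In the Wnt list 2 of 19 rose and 1 fell, the secreted inhibitors Dkk2 and Dkk3 rising by 1.73 (SE 0.25) and 1.23 (SE 0.20) and Rspo3 falling. In the BMP and TGF-beta list 2 of 20 rose, among them Bmp10, and Bmper fell by 0.67 (SE 0.15), and the list passed with fry (adjusted p = 0.0494). In the Notch list 2 of 17 fell, Heyl by 1.27 (SE 0.20) and the ligand Dll1 by 0.88 (SE 0.15). In the retinoic acid list 5 of 16 rose, among them the 3 retinoic acid-degrading enzymes Cyp26b1 (1.35, SE 0.21), Cyp26a1 (1.51, SE 0.27) and Cyp26c1 (2.05, SE 0.37) and the retinal reductase Dhrs3 (1.14, SE 0.18), of which Cyp26c1 was well above background on 1 wild-type array. The other, named after its value was seen, was the receptor Rarb (0.98, SE 0.18), and 3 of the list rose without wild-type pool 2 and 2 without null pool 2. In the hedgehog list 0 of 12 passed, with Shh at -1.58 (SE 0.41, adjusted p = 0.0543) and Gas1 at 0.65 (SE 0.18, adjusted p = 0.0588). Shh passed in 5 alternatives (adjusted p from 0.0056 to 0.0447) and without null pool 1 (0.00957), and Gas1 in 4 (0.0273 to 0.0462). In the Hox list 3 of 22 rose, Hoxd8 by 1.49 (SE 0.20), Hoxb8 by 1.76 (SE 0.41) and Hoxd1 by 1.44 (SE 0.34), Hoxd8 being well above background on 1 wild-type and 2 null arrays, and 1 rose without any pool but wild-type pool 2. With array weights 5 Hox genes rose and 2 fell. The median and the mean of the Hox list differed in sign (-0.13 and 0.11), as did those of the Wnt list (-0.11 and 0.00). Medians were 0.24 for FGF, 0.22 for BMP and TGF-beta, 0.35 for Notch, 0.08 for retinoic acid and -0.04 for hedgehog genes. Adjusted over the list alone the counts risen and fallen were 0 and 0 for FGF, 3 and 1 for Wnt, 2 and 1 for BMP, 0 and 2 for Notch, 5 and 0 for retinoic acid, 1 and 1 for hedgehog and 3 and 0 for Hox genes. Hoxb8 lost its call with quantile normalization (adjusted p = 0.0637), median scaling (0.0512), no filter on dim probes (0.0823) and the authors' value table (0.0537), and Hoxd1 and Bmper with no filter on dim probes (up to 0.0970). Heyl and Dll1 lost their calls with normexp (adjusted p = 0.236 and 0.453), as did Hoxd8 (0.0755). The calls of Dhrs3, Cyp26a1, Cyp26c1, Dll1, Bmper, Hoxb8 and Hoxd1 ended without null pool 2 (adjusted p at most 0.121 with any pool left out). With the slide as a block, Dkk3, Cyp26a1, Dhrs3, Dll1, Bmper and Hoxd1 did not pass (adjusted p from 0.0504 to 0.195), and neither did Rarb.

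Apart from Arid3b, 1 ARID domain gene passed, Jarid2, which rose by 0.79 (SE 0.19, adjusted p = 0.0403, and 0.175 with the slide as a block) and lost its call without any of the 6 pools (adjusted p up to 0.112), with median scaling (0.0860) and with no filter on dim probes (0.101). The list of 13 had a median of 0.44, and 0.37, 0.23 and 0.63 within the slides. Its camera adjusted p = 0.0456 became 0.0610 with the slide as a block and 0.497 with an estimated correlation, and the call ended without wild-type pools 1 and 3 and null pools 1 and 3, each in turn (adjusted p up to 0.159). It also ended with normexp (0.329), array weights (0.240), no filter on dim probes (0.209), the mean of probes (0.117), only probes above background on all 6 arrays (0.0925), the authors' value table (0.0739) and fry (0.0713). Adjusted over the list alone 3 rose and 1 fell. Of 26 oxidative phosphorylation genes, 1 rose and 1 fell, Cox8b by 1.72 (SE 0.32) and the mitochondrial creatine kinase Ckmt2 by -1.6 (SE 0.17), with a median of -0.10 and camera adjusted p = 0.319 (0.0493 with normexp), and adjusted over the list alone 2 rose and 1 fell. Ckmt2 lost its call with normexp (adjusted p = 0.303) and Cox8b without wild-type pool 2 or 3 or null pool 2 or 3 (up to 0.0700). Of 4 measured Y-linked genes, Eif2s3y rose by 0.98 (SE 0.19, adjusted p = 0.0226), and Kdm5d, Uty and Ddx3y did not pass, at 1.08, 0.88 and 0.77, while adjusted over the list alone all 4 rose. Eif2s3y lost its call with the slide as a block (adjusted p = 0.101), with no filter on dim probes (0.0631) and without wild-type pool 2 or 3 or null pool 2 or 3 (up to 0.0865). Xist was at 0.06 (SE 0.44, adjusted p = 0.947). The mean score of the Y-linked genes was 0.21, -0.38 and 0.17 in wild-type pools 1, 2 and 3. In null pools 1, 2 and 3 it was 1.06, 0.98 and 0.74. The sex of the embryos in each pool was not given in the sources used here. A difference in sex makeup between the groups therefore cannot be told apart from genotype.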

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

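The normexp correction on the median spot signal was an alternative chosen after the data were seen, and the others were planned. Arid3b stayed lower and past the threshold under every alternative, from -3.08 to -2.47 log2 units. Of 2273 changed genes (1439 higher, 834 lower), 11 lists and 139 list members in the main comparison, median scaling gave 1435 lower genes, moving the median change of all genes to -0.11 against 0.16 with normexp and 0.17 with no filter. With no filter on dim probes, where 32530 genes were tested, 1037 genes passed (754 higher, 283 lower) and 92 members. Array weights gave 4870 (2796 higher, 2074 lower), 7 lists and 228 members. With the slide as a replicate block 731 passed (532 higher, 199 lower) and 74 members. Pools of the same number did not deviate alike (-0.41, -0.09 and -0.41), which cannot show that the slides had no effect. With an estimated correlation 0 lists passed. Leaving out each pool gave 836 to 1758 changed genes, 590 to 1177 higher, 245 to 581 lower and 78 to 127 members, lowest without wild-type pool 2 or null pool 2. Fewer arrays were left in each such fit, and otherwise the cause was not tested. With normexp Myh3 (0.38), Lmod1 (0.21), Mat1a (0.21), Gcg (0.11) and Ppcdc (0.0199) reversed, and all were not well above background on the null arrays for their brightest probe, where signal over background limits the values. Of 112 called named genes other than Arid3b, 65 kept their call with each pool left out, 71 in the remaining alternatives apart from the block, and 42 lost it with the block.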

Other observations

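All tests in this part, its 3 added gene lists and its marker sets were chosen after the results were seen. A list of targets of ATF4, the transcription factor of the amino acid stress response, was drawn up because several of them were among the risen genes, so its counts are a description and no test. Of 30 measured targets, 21 rose and 0 fell. Besides Chac1, Trib3, Slc7a3 and Stc2 the risen ones included Nupr1, a stress-induced nuclear protein (3.61, SE 0.48), Ddit4, an inhibitor of mTOR signalling (3.14, SE 0.24), the lipoprotein receptor Vldlr (3.01, SE 0.24) and the folate enzyme Aldh1l2 (2.38, SE 0.19).

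A list of pancreatic endocrine genes, several of which neurons also use, was drawn up around genes already seen among the largest falls, so its counts are no test either. Of 19 measured genes, 8 fell and 0 rose, and 5 fell without wild-type pool 2 or 3 or null pool 2. Of the 8, Pnliprp1 belongs to exocrine cells, Neurod1, Gcg and Rfx6 were not well above background on any null array, and Neurog3 was so on 1. Among the others were the transcription factor Insm1 (-1.56, SE 0.34) and the granule protein gene Chgb (-1.02, SE 0.19). Of the other hormone genes, Iapp, Sst, Ins2 and Ppy did not pass, at 0.69, 0.58, 0.33 and -0.05, nor did Ins1, which was not well above background on any null array.

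The 6 arrays can be split into 3 and 3 in 10 ways, and 1 of the 10, the real one, gave 2273 changed genes, while the highest of the others gave 0. So few splits cannot give a share under 0.05. Every other split mixes wild-type and null arrays in both groups, so a real difference between genotypes widens the spread there. Low counts in those splits therefore do not measure how clean the real contrast is.

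The platelet list rose by a median of 2.52 in the null pools. More blood of the wild-type makeup would raise platelet and erythroid transcripts alike if both came from blood alone. The platelet minus erythroid score was higher in the null pools by 1.82 (SE 0.14). The erythroid medians were uneven, at 0.40, 1.84 and 0.26 within slides 1, 2 and 3. Carried-over placental tissue was weighed by leaving out null pool 3, the richest in trophoblast transcript, and the platelet median was then 2.61, while null pool 1, at the wild-type level of trophoblast transcript (score -0.06), scored 2.43. The platelet values without null pool 3 and in null pool 1 argue against tissue carrying trophoblast as the whole cause. The score difference argues against more blood of the wild-type makeup only if both lists come from blood alone, which was not checked. Null pool 1 was, however, not at the wild-type level of hepatic and visceral endoderm transcript. Its score for that list was 1.31, the highest of the null pools, against 0.25, -0.28 and 0.03 in wild-type pools 1, 2 and 3. Carried-over tissue without trophoblast, such as visceral endoderm, was not tested and stays open. More megakaryocytes in the null hearts may also account for the platelet rise. A change in the makeup of the blood and the place of the arrays on the slide stay open and untested.

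The hypoxia list rose by a median of 1.81. With array brightness as a covariate the difference in its score was 1.83 (SE 0.14). By the 75th percentile of log2 signal every null array was dimmer than every wild-type array, so 6 arrays separate brightness from genotype only weakly. Wild-type pool 1 and null pool 1 were nearly alike in it (9.5 and 9.47) but scored -0.09 and 1.86. These values argue against dimmer labelling of the null arrays as the whole cause. Stress during dissection would raise immediate early genes, and 12 of 19 rose, but 6 without wild-type pool 2 or null pool 2, 7 without wild-type pool 1 or 3 or null pool 1, 9 without null pool 3 and 7 with median scaling, so it stays open. Poorer oxygen supply in embryos without Arid3b may also account for the rise and was not tested.

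The median change of 7 neuronal markers was -0.55, against 0.09 for 5 markers of neural progenitors. Less neural tissue of the wild-type makeup would lower both alike, and the neuronal minus progenitor score was lower by 1.14 (-1.14, SE 0.29). That set, however, left out 3 called genes known from neural progenitors, Nkx6-1, Olig3 and Nkx1-2, of which Olig3 was well above background on 0 null arrays and Nkx1-2 on 1. The comparison therefore excludes nothing and less neural tissue stays open. Fewer or later neurons in the null embryos may also account for this and were not tested.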
